A study of Mus musculus with 2 samples.

How the data were processed

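Gene expression was measured in the lung lobes of 2 mouse embryos, 1 heterozygous and 1 homozygous for the Foxj1lacZ allele on an Sv129/CD-1 hybrid background. Per the labels' protocols, tissue outside the lobes was removed, 100 ng of total RNA per embryo was amplified in 1 round into aminoallyl-modified cRNA, and Cy3 (heterozygous) or Cy5 (homozygous) was coupled to it. Titles call the material lung lobes and source names call it lung epithelium. It is treated here as whole lobes, since no step that separates epithelium is described. Both RNAs were hybridised to 1 Agilent 44K-format array, and the 2 deposited scanner files are identical copies of that array, so they count as 1 measurement with 2 channels.

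Spot brightness and local background were deposited as intensity values on a linear scale, and the processed intensity of each channel was background-subtracted and dye-normalized by the scanner software, per the file headers. Agilent Feature Extraction version 9.5.3.1 is named in the submitters' processing notes, and the file headers name linear and LOWESS dye normalization (smoothing factor 0.25), detrending and surrogate values for dim spots. The deposited log ratio is log10 of the red over the green processed signal, per the file headers. The p-value deposited for each spot comes from the software's error model and was used only as a filter in 1 alternative, since it describes these 2 RNA samples and not the genotypes. The series matrix deposited by the authors holds, per probe, the processed intensity of each sample's own channel times 1.68 with a floor of 15. This was found by comparison with the scanner values, from which the SD of the log2 factor was 0.024 and 0.017 for the matching channels and 0.59 for the opposite ones. Its medians were 139.8 for the heterozygous and 138.8 for the homozygous sample, and its scale and direction are settled by that comparison. The reason for the factor remains unknown.

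From the scanner files, the mean signals were corrected with the local median background by normexp with an offset of 50, and the log2 ratios were loess-normalized within the array with control spots at weight 0, in limma 3.58.1 and R 4.3.3 with data.table (version 1.17.8). Control spots and 169 outlier spots were left out afterwards, while saturation affected 0 spots. Spots of a probe were averaged, and 245 probes had 10 spots each. A probe was kept when more than a 0.5 share of its spots was well above background in at least 1 channel, and a gene took the median of its kept probes. The offset pulls ratios of dim probes towards 0, so their changes are understated. Further steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Of 41174 probes, 24375 were named through their transcript accession in a RefSeq gene table of assembly GRCm38.p6, 6301 through their symbol and 2426 through a synonym, and 8072 kept the name in the file. Probe coordinates are those of the files, on mm8, and no coordinate was taken from the gene table. Among 83 genes that differed at least 2-fold and had several probes, 6 had probes of opposite sign.

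With 1 sample per group no test across genes was run and no p-value is given. Genes were counted by a size rule, a log2 ratio of at most −1 or at least 1. For each of 32 gene lists, 6 of them ciliary and the others for cell types or cell states, the median ratio was set against medians of 10000 random lists of the same size matched on mean log2 intensity in 20 bins, and its 95% interval came from 2000 bootstrap draws of its members. A list outside the 2.5 to 97.5 percentile of random lists is called below or above the range, as a description of this array. Of the listed genes, 9 stand in more than 1 list. The error given with a gene is the error of the scanner software's own log ratio on the log2 scale, as the median over the gene's kept probes. It covers spot and channel noise and not the difference between animals or between probes of a gene. A gene well above background in 1 channel only has a bound, its level over the higher of its own value in the other channel and the lowest value of any probe well above background there. Named genes followed a rule set before the data were examined. It takes Foxj1, the 12 largest decreases and the 12 largest increases. The latter come from genes with a symbol in the RefSeq gene table, measured in both channels with all probes of 1 sign, as do the decreases. It also takes the 5 lowest and 2 highest members of each ciliary list and 3 members of each other list outside its random range. Y-linked and reference genes are included, as are genes with 1 measured channel where listed or among the 8 largest bounds. The gene lists and the alternatives were also set then, except where stated. Of the tests of explanations, 2 were narrowed after their values had been seen, with the outcome before narrowing given beside each, and others were chosen or divided after the result was seen, as stated with them.

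The alternatives were no background correction, an offset of 0, the scanner software's log ratio, median centring, the series matrix, stricter and no filters on dim probes, the brightest probe of a gene, outlier spots kept, thresholds of 1.5-fold and 3-fold, the error model's p-value under 0.01, unmatched random lists, list means and lists without shared members. Matching to the nearest 100 genes, leaving out genes at a log2 intensity of 16 or more and leaving out ciliary genes below background in the heterozygous channel were added after the data had been seen. The normalization was tested on simulated data for this comparison, with a dye trend and 200 changed probes among 28170. It called 92.0% of probes made 4-fold lower and 100.0% of those made 4-fold higher at the 2-fold threshold, but 26.0% and 32.0% of those made 2-fold lower or higher, and 0 unchanged ones. The simulated dye trend was a straight line with intensity, with spot noise only and no difference between animals. It lacked the upward bend of the brightest genes described below, so the 0 does not give the rate of false calls on this array. The random-list step was tested on 200 simulated lists of 20 genes among 21171, and 5.5% of unchanged lists and 96.5% of lists shifted by −0.25 fell outside the range. Simulated genes varied independently of each other, with a straight-line shift with intensity and no upward bend. The 5.5% therefore does not give the rate for lists whose members vary together or are very bright.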

Results

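RNA from the lung lobes of 1 heterozygous and 1 homozygous Foxj1lacZ mouse embryo, both male and from the same litter at E16.5, was hybridised to 1 two-colour oligonucleotide array. Foxj1 encodes a forkhead transcription factor known from textbook biology as a driver of motile ciliogenesis, and the series asks which of its effectors are active in the fetal airway. The heterozygous RNA carried Cy3 and the homozygous RNA carried Cy5, with no dye swap. Genotype and dye therefore cannot be told apart, and with 1 lung per genotype no difference given here has a replicate check. All ratios are log2 of homozygous over heterozygous. The value after ± is the scanner software's error for its own log ratio, as the median over the gene's kept probes. It does not cover differences between probes of a gene. As examples among genes named below, probes stood at 1.07 and 2.68 for Ywhaz, 0.16 to 1.82 for Rplp0, −1.76 and −0.61 for Calca, and −1.55 and −0.49 for Fech. The 5 probes of Dync2h1 ran from −0.93 to 0.05. Probes stood at −1.23 and −0.37 for Dnaaf1 and at −3.16 and −2.33 for Tnni3. These examples are not a full list. Of 43379 spots for mouse transcripts, 69.0% were well above background in the heterozygous channel and 75.6% in the homozygous channel. Together 21171 genes were well above background in at least 1 channel, 19206 of them in both. The SD of the log2 ratio between repeated spots of a probe was 0.058 over 214 probes, and between different probes of a gene it was 0.27 over 7144 genes.

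Foxj1 itself was 3.78-fold lower in the homozygous channel, with a log2 ratio of −1.92 ± 0.30 and levels of 9.53 (heterozygous) and 7.61 (homozygous) on the log2 scale. Its single probe lies on chromosome 11 from 116146990 to 116147049 of the mm8 build and was well above background in both channels. Whether that stretch belongs to the part of the gene that the lacZ allele removes was not settled here. If it lies outside that part, the ratio does not check the genotype labels.

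Across the array, 398 genes (1.88% of those detected) were at least 2-fold lower and 122 (0.58%) at least 2-fold higher in the homozygous channel. At 4-fold the counts were 49 and 6. The largest changes are given among genes with a symbol in the RefSeq gene table, measured in both channels with all probes of 1 sign. Of these, 1110017D15Rik had the largest decrease, 17.6-fold lower at −4.14 ± 0.47. It was followed by Fam183b at −3.62 ± 0.41 and by Myl7, the atrial myosin light chain, at −3.52 ± 0.39. Cthrc1, a secreted collagen triple helix repeat protein, stood at −3.33 ± 0.41, Ccdc153 at −3.20 ± 0.46 and Scgb3a1, a secretoglobin of airway secretory cells, at −3.19 ± 0.38. Pifo, a protein of primary cilium disassembly, reached −3.05 ± 0.40 and Meig1, required for sperm flagellum assembly, −3.01 ± 0.36. Efcab10 (−2.98), the transcriptional regulator Prdm16 (−2.86), the dynein light chain Dynlrb2 (−2.80) and Csrp3, the muscle LIM protein (−2.79), completed the 12 largest decreases. The largest increase among the same genes was that of Prim2, the large subunit of DNA primase, 8.22-fold higher at 3.04 ± 0.38. Zfp874a followed at 2.33 ± 0.35, the ribosomal protein gene Rpl41 at 2.15 ± 0.26, the collectin Colec10 at 1.89 ± 0.28, Tescl at 1.88 ± 0.34 and the signalling adaptor Ywhaz at 1.87 ± 0.28. Gdpd3 (1.79), the matricellular gene Ccn3 (1.75), the actin-binding peptide gene Tmsb4x (1.74) and the ribosomal genes Rps14 (1.83), Rplp2 (1.76) and Rps16 (1.74) made up the rest of the 12. The split between lower and higher genes moved with the processing. It was 302 to 724 when ratios were centred on their median in place of loess, 773 to 221 with an offset of 0, and 1143 to 593 with the scanner software's own log ratio, which differs in background and dye correction.

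**Figure D1:**
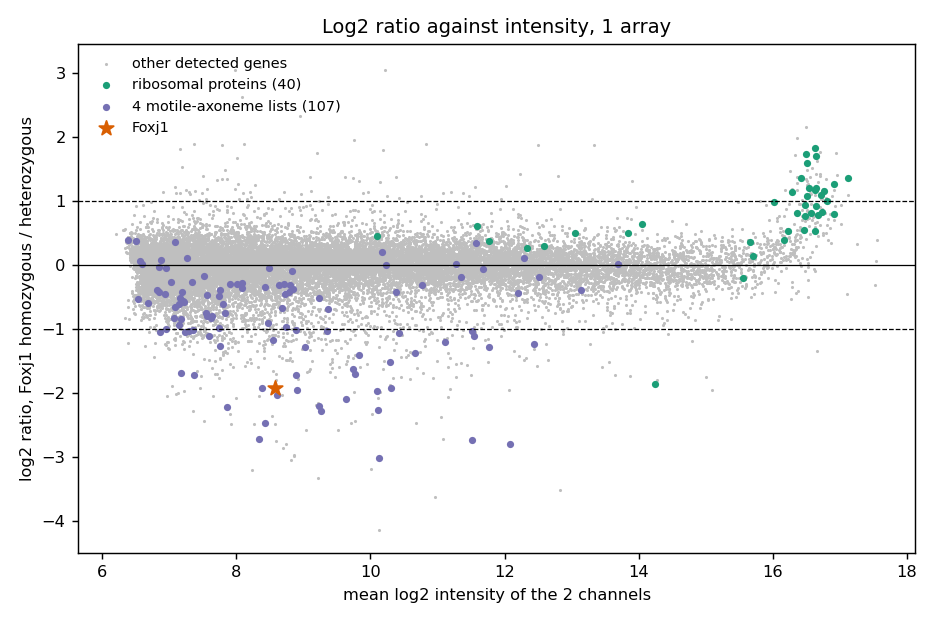
Log2 ratio of homozygous over heterozygous Foxj1 lung (vertical axis) against mean log2 intensity (horizontal axis) for each of 21171 detected genes on 1 array, with the 107 detected genes of the 4 motile-axoneme lists, the 40 ribosomal protein genes and Foxj1 marked and dashed lines at 2-fold. Foxj1 lies at −1.92, 39 of the 107 motile-axoneme genes lie at or below the lower dashed line and none above the upper, and the genes at a log2 intensity of 16 or more bend upwards.

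Genes of the motile axoneme, the microtubule core of beating cilia, were lower in the homozygous channel in all 4 lists drawn up for them. The 107 detected genes of these lists had a median log2 ratio of −0.66 (95% bootstrap interval −0.90 to −0.47), against −0.07 to 0.05 for the central 95% of random gene lists matched on intensity. The pooled median was −0.96 with an offset of 0, −1.08 with the scanner software's log ratio or the series matrix and −0.43 without a filter on dim probes. Of the 107, 95 had a ratio below 0, 39 were at least 2-fold lower and none was 2-fold higher. Among tektins and other microtubule-associated proteins of the axoneme the median was −1.11, or 2.16-fold lower, and 21 of 35 genes were at least 2-fold lower. Meig1, Cfap126 (−2.74 ± 0.33), Cfap161 (−2.47 ± 0.36), 1700007K13Rik (−2.26 ± 0.30) and Ccdc113 (−2.20 ± 0.31) were the lowest, while Mns1 (0.34 ± 0.21) and Nme7 (0.11 ± 0.20) were the highest. The 2 probes of Ak7, an adenylate kinase of this list singled out after its values were seen, differed from each other, at −2.69 and 0.16. For radial spokes, the central pair and the nexin-dynein regulatory complex the median was −0.64, with 12 of 38 genes at least 2-fold lower. The spoke protein Dydc2 (−2.72 ± 0.40), the regulatory complex scaffold Drc1 (−2.28 ± 0.31), Iqcg (−1.93 ± 0.28), Drc3 (−1.72 ± 0.27) and Nme5 (−1.71 ± 0.26) led, and Tcte1 stood highest among those measured in both channels, at 0.36 ± 0.31. Axonemal dyneins had a median of −0.42, with 19 of 22 ratios below 0 and 3 genes at least 2-fold lower. These were Dynlrb2 (−2.80 ± 0.33), Dnali1 (−2.23 ± 0.37) and the heavy chain Dnah8 (−1.28 ± 0.24). Dnah14 was at −0.76 ± 0.25 and Dnah7b at 0.07 ± 0.32. The dynein arm assembly factors had a median of −0.43, with 11 of 13 below 0. Dnajb13 (−1.73 ± 0.36), Zmynd10 (−1.28 ± 0.24) and Lrrc6 (−1.02 ± 0.29) were at least 2-fold lower and Dnaaf1 was at −0.80 ± 0.26, whereas Dnaaf2 (0.02 ± 0.20) and Cfap300 (0.19 ± 0.21) stood near 0. Lists of other cells moved in the same channel, among them airway club and goblet cells with a median of −0.79 and striated and cardiac muscle with −0.27.

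Regulators of the multiciliated-cell programme and of basal body amplification did not stand apart from random lists. Their median was 0.02 over 29 genes, 13 of them below 0, with a random range of −0.12 to 0.10. The cell cycle cyclin Ccna1 was the only member at least 2-fold lower (−1.63 ± 0.26). Deup1, the scaffold of the deuterosome that multiplies centrioles, was at −0.78 ± 0.23, Ccno at −0.37 ± 0.21 and the Notch ligand Jag2 at −0.35 ± 0.21. At the other end stood Rfx5 (0.30 ± 0.33) and Tubgcp2 (0.24 ± 0.21). The members were not alike. The 9 detected ones that act upstream of or beside Foxj1, a set chosen after the result was seen, had a median of −0.26 (interval −0.37 to 0.0029), with 7 below 0. Intraflagellar transport and BBSome genes, which serve primary as well as motile cilia, had a median of −0.07 over 39 genes (random range −0.09 to 0.09), and no member differed by 2-fold. Ttc30b (−0.62 ± 0.21), Ift27 (−0.45 ± 0.21), Dync2h1 (−0.41 ± 0.21), Ift22 (−0.39 ± 0.21) and Bbs9 (−0.37 ± 0.21) were lowest, and Bbs2 (0.52 ± 0.21) and Ttc21b (0.44 ± 0.24) highest. With median centring, which raised the median of all genes by 0.22, the medians of these 2 lists were 0.22 and 0.35.

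**Figure D2:**
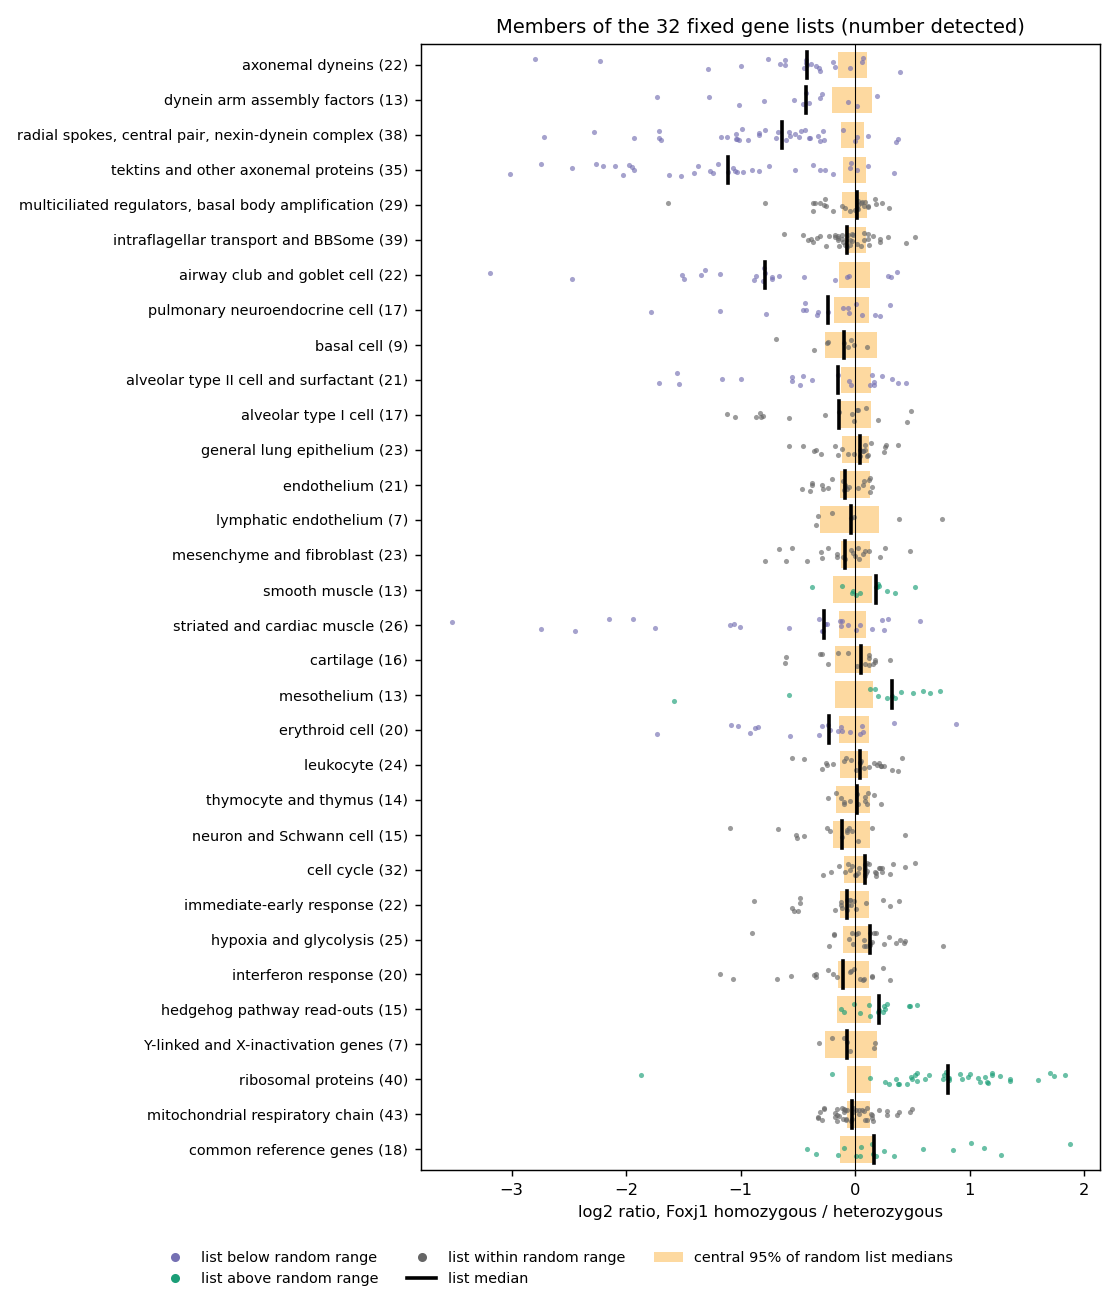
Log2 ratio of homozygous over heterozygous Foxj1 lung (horizontal axis) for the detected members of 32 gene lists (rows, with the number of genes) on 1 array, each point a gene, with the list median as a black bar and the central 95% of medians of intensity-matched random lists as a shaded box. The 4 motile-axoneme lists have medians between −1.11 and −0.42, left of their boxes, and ribosomal proteins lie farthest right at 0.81.

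Transcripts of airway secretory cells also had low ratios, and those of neuroendocrine cells less so. The club and goblet cell list had a median of −0.79 (interval −1.18 to −0.45, random range −0.14 to 0.13), with 7 of 22 genes at least 2-fold lower. Scgb3a1 (−3.19 ± 0.38), the club cell secretoglobin Scgb1a1 (−2.47 ± 0.31) and the cytochrome Cyp2f2 (−1.52 ± 0.25) led it. Pulmonary neuroendocrine genes had a median of −0.24 (interval −0.44 to 0.0066, random range −0.18 to 0.12), with the peptide genes Grp (−1.78 ± 0.26) and Calca (−1.18 ± 0.25) at least 2-fold lower and Scg5 at −0.78 ± 0.25. Surfactant and alveolar type II genes had a median of −0.15, below the random range of −0.13 to 0.13, and 4 of 21 were at least 2-fold lower. The surfactant protein genes Sftpb (−1.72 ± 0.26), Sftpd (−1.56 ± 0.26) and Sftpa1 (−1.54 ± 0.25) were the lowest. The median of this list changed sign, to 0.18, with median centring, and was still below its random lists. General lung epithelial genes, such as transcription factors, keratins and junction proteins, had a median of 0.04 within their random range (−0.12 to 0.12). Basal cell genes (−0.10) and alveolar type I genes (−0.14) also lay within theirs. The type I list left its random range, on the lower side, under 6 alternatives, among them the scanner software's log ratio (−0.18), the mean of the list (−0.31) and median centring, where its median was 0.30.

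Outside the epithelium, striated and cardiac muscle genes had a median of −0.27 (random range −0.14 to 0.10), and 9 of 26 were at least 2-fold lower. Myl7, the cardiac troponins Tnni3 (−2.74 ± 0.39) and Tnnt2 (−2.45 ± 0.32) were the lowest. Erythroid genes had a median of −0.23 (random range −0.14 to 0.12), led by Alas2, the erythroid enzyme of haem synthesis (−1.73 ± 0.26), the haemoglobin chaperone Eraf (−1.08 ± 0.23) and the ferrochelatase Fech (−1.02 ± 0.23). Mesothelial genes lay above their random range at a median of 0.33, with Bnc1 (0.74 ± 0.23), Upk1b (0.65 ± 0.22) and Wt1 (0.59 ± 0.23) highest and 1 of 13 genes at least 2-fold lower, Msln (−1.58), chosen after its value was seen. The value was 0.17 with the mean of the list and 0.83 with median centring, above the range in both. Smooth muscle genes had a median of 0.18, above the random range of −0.19 to 0.15, with Cnn1 (0.52 ± 0.21), Myh11 (0.35 ± 0.21) and Actg2 (0.27 ± 0.21) leading. This list lay within its random range under 4 alternatives, among them the scanner software's log ratio (0.14). Hedgehog pathway read-outs had a median of 0.21, also above the range, with Ccnd1 (0.54 ± 0.21), Mycn (0.48 ± 0.23) and Gli1 (0.47 ± 0.26) highest, and returned to within it with median centring. No gene of the smooth muscle or hedgehog list differed by 2-fold.

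The remaining cell type lists lay within their random ranges. Their medians were −0.09 for endothelium, −0.04 for lymphatic endothelium, −0.09 for mesenchyme and fibroblasts, 0.05 for cartilage, 0.04 for leukocytes, 0.02 for thymocytes and thymus and −0.11 for neurons and Schwann cells. Among the cell state lists, the same held for cell cycle (0.09), immediate-early response (−0.07), hypoxia and glycolysis (0.13), interferon response (−0.10) and the mitochondrial respiratory chain (−0.03). Several of these lists left their range under an alternative. Hypoxia and glycolysis lay above it under 7 alternatives and cell cycle under 2. The respiratory chain lay below it with the scanner software's log ratio or the series matrix (−0.12), and immediate-early genes with median centring. With the brightest probe of each gene, the lists for endothelium (−0.16), mesenchyme (−0.16), neurons (−0.24) and interferon response (−0.21) lay below it. The neuron list did so as well with probes above background in both channels, and the mesenchyme list with median centring. In all, 9 of the 32 lists lay below and 5 above the central 95% of random lists. By chance 1.6 would be outside if the members of each list varied like genes drawn at random. Genes of a cell type or state may vary together, so 1.6 does not show how many would be outside without a genotype effect.

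Ribosomal protein genes had the highest list median, 0.81 (interval 0.57 to 1.03), with 15 of 40 genes at least 2-fold higher. The median was 0.47 with the scanner software's log ratio or the series matrix and 1.81 with median centring. Rps14 (1.83 ± 0.24) and Rps16 (1.74 ± 0.24) led. The 168 non-ribosomal genes at a log2 intensity from 16 to 17 had a median of 0.39 as well, and 53 of the 122 genes at least 2-fold higher lay at a log2 intensity of 16 or more. Common reference genes had a median of 0.17. The bright Gapdh (0.60 ± 0.21), Rplp0 (0.86 ± 0.21), Eef1a1 (1.01 ± 0.21), Rpl13a (1.13 ± 0.21) and Ppia (1.27 ± 0.22), together with Ywhaz, were highest. Dimmer members such as Gusb (0.06 ± 0.20), Eef2 (0.01 ± 0.20), Polr2a (−0.10 ± 0.21) and B2m (−0.15 ± 0.21) stood near 0, and Tfrc was at −0.35 ± 0.21. Actb was at 0.25 ± 0.21, Tbp at 0.34 ± 0.21, Pgk1 at 0.18 ± 0.20, Sdha at 0.15 ± 0.21 and Hprt at 0.04 ± 0.20. The reference list lay within its random range with outlier spots kept (0.16), and also without very bright genes or with each gene matched to the 100 nearest in intensity, 2 comparisons added after the data had been seen.

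The 207 detected genes within 5 Mb of Foxj1, which could carry another strain's chromosome beside the mutant allele, had a median of 0.03 within the random range of −0.04 to 0.04. It lay above that of its own random lists with probes above background in both channels (percentile 98.05) or no filter on dim probes (percentile 99.6). Of these, 3 were at least 2-fold lower and 1 was 2-fold higher. Y-linked genes were measured in both channels, which fits the labels of 2 male embryos. Eif2s3y stood at −0.04 ± 0.20, Ddx3y at −0.10 ± 0.21, Kdm5d at −0.31 ± 0.21, Uty at 0.16 ± 0.24, Zfy1 at −0.07 ± 0.25 and Zfy2 at −0.20 ± 0.35. The list of Y-linked genes and Xist had a median of −0.07, and Xist, at log2 levels of 6.50 and 6.67, was well above background in the homozygous channel only.

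A further 271 genes were well above background in the heterozygous channel only, and 1694 in the homozygous channel only. For these a ratio is a bound, open to dye bias, and of the 1694 only 936 have a bound above 1, the others leaving the direction undetermined. The radial spoke head gene Rsph4a was at least 3.23-fold lower in the homozygous channel, Zfp605 at least 5.34-fold, Zfp474 at least 4.53-fold, Tmem212 at least 3.52-fold and Spink6 at least 3.19-fold. Among listed genes with smaller bounds, the dynein heavy chain Dnah6 was at least 1.996-fold lower and the assembly factor Daw1 at least 1.40-fold lower. In the other direction the mast cell tryptase Tpsab1 was at least 3.24-fold higher, Phyhip at least 2.24-fold and the spoke list's Cfap46 at least 1.05-fold. These bounds take no account of measurement error. On the log2 scale the bounds of Daw1 (0.49) and Cfap46 (0.066) were smaller than the scanner errors of these genes (0.56 and 0.86). For them a minimum change is therefore not settled. Transcripts with predicted-only names made up 6 of the 8 largest bounds in this direction, the largest at least 7.38-fold and the next at least 6.18-fold higher, and 3 of the 8 in the other. With such genes set to their bounds, 394 genes were at least 2-fold lower and 121 higher, and no list median moved by more than 0.012.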

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

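The tests on cartilage, on general epithelium, on random lists under other dye settings and on the genes nearest in intensity were chosen only after the result was seen, and the last was also divided at a log2 intensity of 16 after its undivided outcome was known. The cartilage test took the place of one on general epithelium for the ciliary lists, whose value is still given, and a condition on the SD was added to the general epithelium test of the second pattern, which left its outcome for the club part as it was. That test was also divided into a club and a surfactant part after its values were seen.

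Spike-in control probes of the array design, which the comparison does not use, carried signal although the labels do not mention added control RNA. Of 10 such probes (320 spots), 8 were well above background in both channels, with a median log2 ratio of −1.03 and a range from −1.27 to 0.48. The brightest was the only one of these above 0, with −0.82 and −1.19 for the next 2, so control probes too bend upwards at the top intensities. Since the labels do not say whether equal amounts were added, the ratio near −1 leaves the scaling between channels unsettled.

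The first pattern is the low ratio of the 4 motile-axoneme lists. A trend of the ratio with intensity left by the normalization is argued against as the whole source, by the comparison with random lists matched on intensity. Over 5 other background and dye settings the list median nearest 0 was −0.20, and each of the 4 lists stayed below random lists matched on intensity. The rule of the test asked only for medians beyond the SD of repeated spots (0.058). That is not the spread of a list median, so meeting the rule adds little. No background correction and an offset of 0 keep the same loess step, and median centring removes no trend with intensity. Of these settings, the scanner software's log ratio and the series matrix hold nearly the same ratios and are not separate checks. All of them use the same array without a dye swap. Airway with cartilage from outside the lobes, left on the heterozygous lung, is argued against as the whole source, since the cartilage list had a median of 0.051 (interval −0.24 to 0.12) against −0.66 (−0.90 to −0.47) for the motile-axoneme genes. Fewer airway epithelial cells in the homozygous lobes stays open in part. In the main setting the club and goblet cell median (−0.79) lay below that of the ciliary genes, while the neuroendocrine (−0.24) and general epithelial (0.043) medians did not. The ciliary median was the lower with an offset of 0 (−0.96 against −0.86), the scanner software's ratio or the series matrix (−1.08 against −0.89) and median centring (−0.67 against −0.37). There the rule of the test was met against this explanation. Its margin was the SD of repeated spots (0.058), which is not the spread of a list median, so that outcome cannot decide. In the main setting the intervals overlapped, at −0.90 to −0.47 for the ciliary genes and −1.18 to −0.45 for the club list. The cartilage list does not speak to other tissue, and a difference in the dissected tissue stays open for the ciliary lists as well. Of 26 striated and cardiac muscle genes, 9 were at least 2-fold lower, such as Myl7 (−3.52), and 7 were above 0. Genotype, a dye preference of single probes and the difference between 2 littermates also stay open, untested, as the design joins them.

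The second pattern is the low ratio of club cell and surfactant transcripts. For the club cell part, a general loss of epithelial cells is argued against as the whole cause by the general epithelial median of 0.043, which lies above the club median by more than the SD of the epithelial members (0.25), whereas the surfactant median (−0.15) is within that SD of it and leaves the explanation open there in the main setting, though the gap exceeded that SD under 7 alternatives, such as the scanner software's ratio (0.072 against −0.31) and the brightest probe (0.043 against −0.31). A homozygous embryo at an earlier stage of development may contribute, since transcripts that decline during fetal development, such as Igf2 (chosen after its value was seen, 0.45), had a median of 0.25 with 11 of 11 above 0 (percentile 99.5 of random lists). The other part of that test did not reach its bound in the main setting, where 9 further late-gestation lung transcripts had a median of −0.13 within their random range, but they lay below it with the brightest probe (−0.32), the mean (−0.33) or median centring (0.040, where the median of all genes was 0.22), so both parts were met there and stage cannot be told apart from genotype for these genes, nor for the ciliary ones. Tissue composition stays open too, with the striated and cardiac muscle list at a median of −0.27 and mesothelium at 0.33.

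The third pattern is the high ratio of ribosomal protein transcripts. For the 28 members at a log2 intensity of 16 or more (median 1.04, interval 0.82 to 1.18), the non-ribosomal genes nearest in intensity stood at 0.70 (0.42 to 0.97), so a trend left among the brightest probes may account for much of it and cannot be told apart from a change of these genes. For the 12 dimmer members, such a trend is argued against, since their median was 0.36 (0.20 to 0.49) and that of the nearest genes was −0.090 (−0.25 to 0.15). Rpl14, chosen after its value was seen, went the other way at −1.87. Before the division, the 40 nearest genes stood at 0.41 (0.07 to 0.71) against 0.81 for all ribosomal members, which left a trend undecided for the whole list, so the case against it for the dimmer members rests on a division made with the values in view.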

How the results depend on the processing

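The 3 alternatives added after the data were seen are the nearest-gene matching, the set without very bright genes and the ciliary lists without members below background in the heterozygous channel. All 4 motile-axoneme lists stayed below their random lists under every alternative run on them, but some values moved, and the cause was not tested except where the threshold itself sets it. Genes at least 2-fold lower, 398 in the main setting, numbered 773 with an offset of 0, 1143 with the scanner software's log ratio and 1139 with the series matrix, of which 398, 395 and 395 were shared, and 1243 and 105 at 1.5-fold and 3-fold. Genes at least 2-fold higher, 122 in the main setting, numbered 221, 593 and 457 in the same 3 settings, 724 with median centring, 69 without very bright genes, and 444 and 26 at 1.5-fold and 3-fold. Only 83 of the 122 were shared with the scanner software's ratio, and 235 of the 398 lower genes with median centring. Foxj1 was at −2.33 with the scanner software's ratio and the series matrix. In those 2 settings the radial spoke list was at −1.15 and genes near Foxj1 at 0.066. With median centring, which raised the median of all genes by 0.22, dynein arm assembly factors were at −0.20, regulators at 0.22, intraflagellar transport at 0.35 and genes near Foxj1 at 0.35, and the surfactant list reversed to 0.18. Without a filter on dim probes, axonemal dyneins were at −0.20 and radial spokes at −0.44. The brightest probe put the dyneins at −0.63, and the mean put genes near Foxj1 at −0.021. Of 1122 values of 127 other named genes, 883 stayed within the scanner error, 239 moved by more, and 0 reversed among genes past 2-fold. A gene with 1 probe cannot change under the filters on dim probes or the brightest probe. Without outlier spots it cannot change when such spots are kept either. Such unchanged values count among the 883, so that number does not measure how stable the genes are. Signal over background limits the 271 and 1694 genes measured in 1 channel to bounds.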

Other observations

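The test of upstream genes was chosen only after the result was seen, its limit on level was set after the values of its members were seen, and the genes named in the first paragraph were chosen after their values were seen.

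Within the alveolar lists, genes did not move together. Alveolar type I genes Akap5 (−1.05), Hopx (−0.87), Ager (−0.83), Aqp5 (−0.83) and Emp2 (−0.81) were low beside Igfbp2 at 0.49 and Col4a4 at 0.45. In the type II list Cxcl15 (−1.16) and Napsa (−0.99) were low beside Sftpc, the bright surfactant protein gene, at 0.33. Among erythroid genes the embryonic globin Hba-x stood at 0.88 while the adult globin Hba-a1 was at 0.06. Mesothelial Msln was at −1.58 although 11 of the 13 genes of its list were above 0. The sodium channel subunit Scnn1a (−1.23) and the water channel Aqp1 (−0.95) were the lowest of the late-gestation lung transcripts. In the heart and muscle list, Myl4 (−1.94), Tnni1 (−2.15) and Tnnc1 (−1.75) were low, while Actc1, among its brightest members, was at −0.07.

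One hypothesis is that fewer cells entered the multiciliated programme in the homozygous lobes, rather than the same cells making less of the axoneme. As first set, the test took all 9 detected genes that act upstream of or beside Foxj1, and it argued against the hypothesis, with a median of −0.26 and an interval (−0.37 to 0.0029) wholly above the −0.90 to −0.47 of the motile-axoneme genes. A limit was then added, a log2 level of 8 in the heterozygous channel, because dim genes have little room to fall, and it left 5. Deup1 (−0.78), Ccno (−0.37), Trp73 (−0.31), Myb (−0.27) and Ccdc78 (−0.26) were all below 0, with a median of −0.31 and an interval from −0.78 to −0.26. With the limit the interval overlaps that of the motile-axoneme genes, although the list lay within its random range, and the hypothesis is undecided. Since the change from a negative to an open outcome came from a limit set with the values in view, the open outcome carries no more weight than the negative one.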
